A study of Homo sapiens with 12 samples.

How the data were processed

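RNA was sequenced from polarized hepatocyte organoids (P-hep-orgs), three-dimensional cultures of hepatocyte-like cells differentiated from H9, an established human embryonic stem cell line. Organoids were treated with free fatty acids (FFAs) for 2 or 10 days, and each duration had its own control without FFAs, which gave 4 groups of 3 libraries and 12 libraries in all. Per the labels, total RNA was extracted with RNAiso Plus and libraries were made with a NEBNext Ultra RNA kit for Illumina. The strand setting, the fatty acids, their dose and the carrier given to the controls are not stated in the labels.

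The values analysed were the raw read counts per gene that the authors deposited, whole numbers with no normalization, in 1 table for day 2 and 1 table for day 10. The submitters' processing notes name the genome build GRCh38 and DESeq2, with no version. The aligner, the counting tool and the annotation release are not given in the sources used here. The 2 tables did not use the same annotation. The day 2 table listed 36601 Ensembl genes, of which 10311 were at 0 in all 6 libraries. The day 10 table listed 33441 genes, none of them at 0 in all 6 libraries. They shared 24715 identifiers, which held 99.8% of the day 2 counts and 98.8% of the day 10 counts. Genes that overlap others can be counted differently by the 2 annotations. CD68, chosen as an example after its values were seen, had 496 CPM (counts scaled to the library size) in the day 2 controls and 0.210 CPM of the library totals in the day 10 controls. For this reason the controls of the 2 days were not tested against each other. Genes were matched by Ensembl identifier without its version. Gene symbols came from a reference table of current gene names, or from GENCODE 29 where that table had none. Coordinates, gene type, transcript length and GC content were taken from GENCODE 29, an annotation of GRCh38. A symbol was found for 36585 of the day 2 genes and 33161 of the day 10 genes.

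Each day was fitted on its own with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its defaults, which left 14823 genes for day 2 and 15278 for day 10. Libraries were scaled by TMM, a quasi-likelihood model with robust dispersion and a term for treatment was fitted, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called higher or lower at an adjusted p (FDR) under 0.05. Standard errors (SE) of log2 fold changes were derived from the fitted coefficient and its F statistic. Levels are given as CPM scaled by TMM within a day, as mean and standard deviation (SD) of 3 libraries, unless CPM of the library totals are named. The difference between days was the contrast of the FFA effect at day 10 minus the FFA effect at day 2 in a fit of all 12 libraries on the shared identifiers, of which 15350 passed the filter. That contrast had been planned for tables of the same annotation only. It was run although the annotations differed, on the assumption that a difference in counting cancels within each day. Overlap between the calls of the 2 days was tested with a Fisher's exact test per direction, one-sided, among the genes tested on both days.

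The 30 gene lists, with 911 entries, had been written from textbook knowledge before the data were examined, and 29 of them had at least 5 tested members in each comparison. The list of pluripotency and early germ layer markers had fewer. Lists were tested with camera in limma 3.58.1 with the preset inter-gene correlation of 0.01, and adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Fry asks whether the members of a list move on balance in 1 direction and does not compare them with other genes. Members were counted as called over all genes tested and also adjusted over the list alone. The genes named in the text follow a rule that was fixed in advance. Per day it takes the 10 genes with the largest change in each direction among those past FDR 0.05 with a mean of at least 5 CPM, no overlap between the groups and an established gene symbol. It adds the 2 to 4 members of smallest FDR of each list described, the 10 genes of smallest FDR for the difference between days, and a set of genes named whatever their result. Some genes and 1 gene list that fall under this rule are not reported here. Genes outside the rule are marked as chosen after their values were seen.

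Depth was 15459675 to 18566753 counts per library. A floor of 3 counts, the upper limit that a count of 0 allows, corresponded to 0.162 to 0.194 CPM. Such floors and the Wilson 95% confidence intervals given for shares cover counting error only, since reads without molecular identifiers are not independent molecules. The fits were tested on simulated counts with the mean levels of the control libraries, the dispersions estimated from all libraries of the comparison and known changes in some genes. At day 2 the settings recovered 56.1% of genes changed 1.5-fold, 79.7% of those changed 2-fold and 98.5% of those changed 4-fold, and 9.60% of the calls were false. At day 10 the shares were 69.7%, 87.9% and 100%, with 7.44% false calls. For the difference between days they were 29.9%, 69.7% and 85.9%, with 4.65% false calls. A list shifted by a small amount was recovered in each comparison, and 2, 0 and 1 of 27 unshifted lists were called. Genes were simulated independently of each other. The simulation therefore does not show how often lists of correlated genes are called falsely.

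Alternatives covered DESeq2 size factors and library totals as scaling, 2 other filters on low counts, DESeq2 1.42.0 and limma voom as test tools, the replicate number as a block, a stricter FDR of 0.01, a fold threshold, a shared fit of all 12 libraries, and leaving out each library in turn. After the data had been seen, a correction that removed the loess trend of each library against transcript GC content was added, as was leaving out FFA replicate 2 of day 2 for the overlap and for the counts of called members within lists. Reads shared between near-identical genes were not resolved, so the values of CCL4L2, RN7SL1, ORM1, SAA1, SAA2, AKR1C1 and the metallothionein genes are uncertain in their assignment. The p-values measure only the spread between these libraries. No source says that the replicates were separate cultures, so they may be technical. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.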

Results

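Polarized hepatocyte organoids from H9 human embryonic stem cells were sequenced after 2 and 10 days with or without FFAs, a culture model of metabolic dysfunction-associated steatotic liver disease. There were 3 libraries in each of 4 groups. At day 2 the controls held 15729797, 15976051 and 15493669 counts and the FFA libraries 15951102, 17503320 and 15459675. At day 10 the controls held 15809303, 15951861 and 16434522 counts and the FFA libraries 18566753, 18036378 and 15928431. AFP, which encodes alpha-fetoprotein, was a large part of every library. It took 9.91% ± 0.06 (SD, n = 3) of the counts in the day 2 controls, 9.30% ± 1.53 in the day 2 FFA libraries, 13.4% ± 0.12 in the day 10 controls and 8.46% ± 0.08 in the day 10 FFA libraries. FFA replicate 2 of day 2 stood apart from the other 2 FFA libraries of its day. AFP took 11.1% of its counts (95% confidence interval 11.05% to 11.08%), against 8.31% (8.30% to 8.33%) and 8.52% (8.51% to 8.54%) in the others. Across 10470 genes, its deviation from these 2 libraries followed the GC content of the transcripts, with a Spearman correlation of -0.795, while the same measure between the other 2 FFA libraries was -0.0263. Genes are not independent replicates, so these are descriptions.

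The day 2 comparison asked which transcripts respond early to FFAs. Genes of fatty acid oxidation and genes of lipid storage rose. PDK4, a kinase that inhibits pyruvate dehydrogenase, went from 51.5 ± 2.7 CPM in controls to 383 ± 38.9 CPM with FFAs (SD, n = 3), a 7.43-fold rise. CPT1A, which commits long-chain fatty acids to mitochondrial oxidation, rose 6.51-fold, and PLIN2, a coat protein of lipid droplets, rose 4.22-fold. Genes of hepatocyte secretion fell, among them ALB, which encodes albumin, from 11967 ± 213 to 8070 ± 977 CPM. In all, 508 of 14823 genes tested were higher and 581 were lower at FDR 0.05, and 68 and 129 of these changed at least 2-fold.

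PDK4 (ENSG00000004799) is a protein-coding gene on chromosome 7, from 95583499 to 95596491 on GRCh38, and its log2 fold change was 2.89 ± 0.09 (SE, n = 3 per group, adjusted p = 2.9e-09). CPT1A (ENSG00000110090, chromosome 11, 68754620 to 68844410) changed by 2.70 ± 0.09 with an adjusted p of 2.9e-09. PLIN2 (ENSG00000147872, chromosome 9, 19108375 to 19149290) changed by 2.08 ± 0.08. Other genes with large rises were MS4A10, a membrane protein (2.76 ± 0.19), FABP2, the intestinal fatty acid-binding protein (2.43 ± 0.14), SLC38A4, an amino acid transporter (1.98 ± 0.24), C3orf85 (1.87 ± 0.12), GADD45B, a stress-responsive gene (1.86 ± 0.17), and ACSL5, an acyl-CoA synthetase (1.80 ± 0.07). Among genes at a mean of 5 CPM or more, the largest falls were in the carbonic anhydrases CA1 (ENSG00000133742, chromosome 8, 85327608 to 85379014, -2.52 ± 0.18) and CA3 (-1.79 ± 0.11). At that level they were followed by DIO1, a thyroid hormone deiodinase (-1.55 ± 0.17), the annexin ANXA13 (-1.52 ± 0.08), the NADPH oxidase NOX1 (-1.49 ± 0.12), WIF1, a secreted inhibitor of WNT signalling (-1.48 ± 0.19), the axonemal dynein gene DNAH12 (-1.47 ± 0.10), ITIH2 (-1.43 ± 0.17), COL2A1 (-1.41 ± 0.15) and VCAN, which encodes versican (-1.38 ± 0.16). All 3 FFA libraries lay on the same side of all 3 controls for each of these genes, which was a condition of the rule that chose them.

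**Figure D1:**
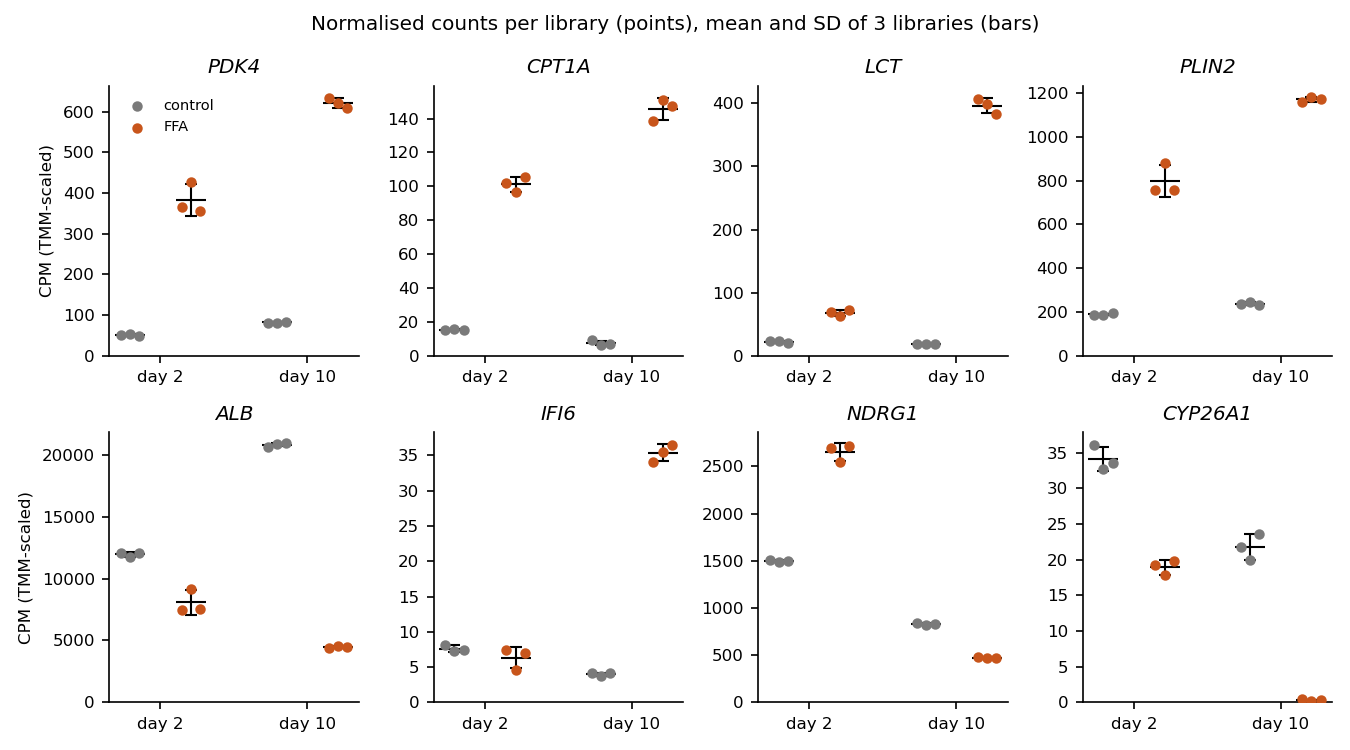
TMM-scaled CPM (vertical axes, from 0) of 8 genes in each of the 12 libraries, with points for libraries and bars for the mean and SD of 3 libraries, control and FFA side by side for day 2 and day 10. CPT1A and LCT were higher with FFAs on both days, ALB fell to 4485 CPM at day 10, and NDRG1 was higher with FFAs at day 2 and lower at day 10.

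Of the 35 tested genes of fatty acid oxidation and ketogenesis, 18 were higher and 0 lower at day 2 (20 and 0 adjusted over the list alone), with a median log2 fold change of 0.35. ANGPTL4, an inhibitor of lipoprotein lipase, rose by 0.89 ± 0.20. Of 28 lipid droplet genes, 7 were higher and 1 lower (9 and 1 adjusted over the list alone). Among them, HILPDA, an inhibitor of lipolysis, rose by 0.95 ± 0.10, the droplet protein gene CIDEC by 0.61 ± 0.07 and DGAT2, an enzyme of triglyceride synthesis, by 0.67 ± 0.08. Of 27 cholesterol synthesis genes, 7 were higher and 0 lower (8 and 0 adjusted over the list alone), including INSIG1 (0.56 ± 0.07), CYP51A1 (0.48 ± 0.07) and DHCR7 (0.56 ± 0.08). This list passed camera, with an adjusted p = 0.0791 with an estimated correlation. Of 33 glycolysis and hypoxia genes, 17 were higher and 0 lower (24 and 1 adjusted over the list alone). NDRG1, a hypoxia-inducible gene, rose by 0.83 ± 0.07, the glucose transporter gene SLC2A3 by 1.31 ± 0.15, ENO2 by 0.69 ± 0.08 and ADM by 0.74 ± 0.09. Of 5 tested genes of the metallothionein list, which also holds the zinc transporter gene SLC30A1, 3 were higher, MT1F, MT1G and MT2A, at under 4 CPM (5 adjusted over the list alone, SLC30A1 among them, adjusted p = 0.0990 with an estimated correlation). Of 21 interferon-stimulated genes, 4 were higher and 0 lower (7 and 0 adjusted over the list alone), OAS1, HERC6, IFIT2 and HERC5, with an adjusted p = 0.0990 with an estimated correlation. None of 40 nuclear-encoded oxidative phosphorylation genes was called over all genes or over the list alone, although camera placed the list higher as a whole (median 0.12, adjusted p = 0.0155). With an estimated correlation its adjusted p = 0.584.

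Of 33 hepatocyte secretory and urea cycle genes, 10 were lower and 0 higher at day 2 (16 and 1 adjusted over the list alone). PROC, which encodes protein C, fell by 1.11 ± 0.11, TTR, which encodes transthyretin, by 0.75 ± 0.09, VTN by 0.59 ± 0.08 and prothrombin, F2, by 0.73 ± 0.10. The acute phase and complement list had 6 of 20 members lower and 0 higher (9 and 0 adjusted over the list alone, median -0.47), with C3 at -0.88 ± 0.08, SAA1 at -1.32 ± 0.15 and LCN2 at -1.28 ± 0.19. The extracellular matrix list had 8 of 34 members lower and 0 higher (16 and 1 adjusted over the list alone), with CCN2 at -1.28 ± 0.09, COL5A2 at -1.03 ± 0.09 and decorin, DCN, at -1.62 ± 0.21. COL1A1 was at 0.18 ± 0.15 and not called. Of 20 cholangiocyte markers, 5 were lower and 0 higher (5 and 0 adjusted over the list alone), including SOX9 (-0.69 ± 0.14) and KRT19 (-0.47 ± 0.12). Both of these lists had an adjusted p = 0.0990 with an estimated correlation. Of 35 drug metabolism genes, 2 were higher and 8 lower (2 and 11 adjusted over the list alone). CYP1A1 fell by 1.04 ± 0.08 and CYP2B6 by 0.58 ± 0.10, CYP2J2 rose by 1.86 ± 0.30, and CYP3A4 was at -0.03 ± 0.17. The adjusted p = 0.412 with an estimated correlation for this list.

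The other lists did not pass camera at day 2. Of 23 lipogenesis genes, 1 was higher and 3 lower. SREBF1, a regulator of lipid synthesis, fell by 0.60 ± 0.15 and INSIG2 rose by 0.63 ± 0.08, while FASN was at -0.29 ± 0.16 and SCD at 0.08 ± 0.06 and neither was called. Of 20 lipoprotein genes, 3 were higher and 4 lower. APOA4 rose by 1.56 ± 0.07, the cholesterol exporter gene ABCA1 fell by 0.90 ± 0.07 and APOB was at 0.13 ± 0.07. Of 27 bile acid genes, 3 were higher and 2 lower, with the bile salt export pump ABCB11 at -2.11 ± 0.24, and the median of the list (0.04) and its mean (-0.11) differed in sign. CYP7A1, the rate-limiting enzyme of bile acid synthesis, had 0 counts in all 6 libraries. Of 34 genes of the unfolded protein and integrated stress responses, 4 were higher and 6 lower, and DDIT3 was at -0.13 ± 0.12. Higher and lower members were 4 and 2 of 30 NFE2L2 targets, 1 and 3 of 27 NF-kB targets, 2 and 5 of 23 gluconeogenesis genes, 6 and 0 of 21 immediate early genes, and 2 and 1 of 38 polarity genes. PCK1, a gluconeogenic enzyme, rose by 1.39 ± 0.10. Fetal liver markers had 1 and 1 of 15, stellate cell markers 1 and 0 of 9, endothelial and macrophage markers 0 and 0 of 9, intestinal markers 3 and 6 of 20, cell cycle genes 0 and 1 of 23, mitochondrially encoded genes 0 and 0 of 13, and ribosomal proteins 0 and 0 of 49. CXCL8, a chemokine, had 3 to 8 counts per library and was not tested.

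The day 2 counts depended on single libraries. Without FFA replicate 2, the library that stood apart, 3217 genes were called, and 1080 of the 1089 were among them. Without control replicate 1, 2 or 3 the counts were 427, 439 and 420, and without FFA replicate 3 it was 694. With the GC trend of each library removed, 2649 genes were called, among them FASN (-0.16) and COL1A1 (0.28). The day 2 log2 fold changes themselves had a Spearman correlation of -0.363 with GC content across genes. Without FFA replicate 2 the direction of the fatty acid oxidation (22 higher, 1 lower), glycolysis (28 and 3), hepatocyte (1 and 20) and acute phase (1 and 8) lists was unchanged and each stayed past FDR 0.05. The extracellular matrix list also stayed past it but then had 9 higher and 15 lower, and with the GC trend removed 4 and 15. The interferon list (adjusted p = 0.0902) and the oxidative phosphorylation list (adjusted p = 0.191) were then not called. The ribosomal protein list was then called lower (median -0.13, 31 of 49 lower). So were the unfolded protein and integrated stress response list (-0.11) and the mitochondrially encoded list (6 of 13 lower, camera adjusted p = 0.0329). The intestinal and immediate early lists were called higher, with medians of -0.13 and 0.01. The drug metabolism list was not called without FFA replicate 1 (adjusted p = 0.0924).

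The day 10 comparison asked how organoids kept in FFAs for longer differ from controls of the same age. Fatty acid oxidation genes were again among the genes that rose most, interferon-stimulated genes rose, and hepatocyte secretory genes fell. CPT1A went from 7.70 ± 1.27 to 145 ± 6.5 CPM (SD, n = 3), an 18.9-fold rise. ALB fell from 20824 ± 146 to 4485 ± 64 CPM, a 4.64-fold fall. CYP26A1, which degrades retinoic acid, fell from 21.8 ± 1.8 to 0.32 ± 0.08 CPM, a level resting on a few counts per library. In all, 3528 of 15278 genes tested were higher and 3373 lower, and 463 and 551 of these changed at least 2-fold. The fitted coefficient of variation between libraries was 0.0337, against 0.103 at day 2. Counts of called genes therefore do not compare the size of the response between the days.

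CPT1A had a log2 fold change of 4.24 ± 0.07 (SE, n = 3 per group, adjusted p = 2.3e-65). LCT, which encodes intestinal lactase (ENSG00000115850, chromosome 2, 135787840 to 135837180), rose by 4.42 ± 0.04 and reached 396 ± 12 CPM. Among the largest rises at a mean of 5 CPM or more were the interferon-stimulated genes RSAD2 (ENSG00000134321, chromosome 2, 6865806 to 6898239, 4.41 ± 0.23, from 0.50 ± 0.20 CPM), IFI6 (3.14 ± 0.10), OASL (3.04 ± 0.20) and IFIT2, which went from 2.69 ± 0.98 to 21.7 ± 1.5 CPM. The chemokine gene CCL4L2 (3.58 ± 0.13), MS4A10 (2.96 ± 0.11) and PDK4 (2.92 ± 0.03) rose too. CYP26A1 (ENSG00000095596, chromosome 10, 93073475 to 93077890) fell by 6.03 ± 0.20, and CYP26B1, another retinoic acid-degrading enzyme (ENSG00000003137, chromosome 2, 72129238 to 72148038), by 3.14 ± 0.07. GC, which encodes the vitamin D-binding protein (ENSG00000145321, chromosome 4, 71741693 to 71804041), fell by 5.26 ± 0.05, from 328 ± 6.2 to 8.58 ± 1.15 CPM. Other large falls at that level were in RN7SL1, an RNA of the signal recognition particle with widely spread controls (-4.87 ± 0.64), GLYAT, a glycine acyltransferase (-3.62 ± 0.14), NOX1 (-3.26 ± 0.10), the RNA-binding protein gene CELF3 (-2.91 ± 0.21), ORM1, an acute phase protein (-2.62 ± 0.06), SLC2A5, a fructose transporter (-2.59 ± 0.09), and DNAH12 (-2.40 ± 0.09).

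Of 34 fatty acid oxidation genes, 19 were higher and 8 lower at day 10 (19 and 8 adjusted over the list alone), with ACSL5 at 1.68 ± 0.02 beside PDK4 and CPT1A. ANGPTL4 was at 0.45 ± 0.19 with an adjusted p of 0.0461, and with the GC trend removed it was not called (0.38, adjusted p = 0.101). Of 26 lipid droplet genes, 12 were higher and 4 lower (12 and 4 adjusted over the list alone). PLIN2 rose by 2.30 ± 0.03, from 239 ± 7.4 to 1171 ± 10.5 CPM, and CIDEC by 0.74 ± 0.03, while G0S2, an inhibitor of triglyceride lipase, fell from 19.6 ± 0.6 to 3.71 ± 0.54 CPM. Of 27 cholesterol synthesis genes, 14 were higher and 4 lower (15 and 4 adjusted over the list alone). INSIG1 rose by 0.42 ± 0.03 and LSS by 0.57 ± 0.04, while the intestinal cholesterol transporter gene NPC1L1 fell by 0.54 ± 0.03. That list had a camera adjusted p of 0.0486 and an adjusted p = 0.142 with an estimated correlation. It was not called without control replicate 3 (0.0507) or FFA replicate 3 (0.0522), or with DESeq2 size factors (0.0538).

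Of 26 interferon-stimulated genes, 23 were higher and 1 lower (23 and 1 adjusted over the list alone), with a median log2 fold change of 2.21. OAS1 rose by 2.26 ± 0.08, OAS3 by 2.21 ± 0.07 and IFI27 by 2.22 ± 0.10, all to levels under 60 CPM. Of 21 immediate early and dissociation stress genes, which also respond to handling, 20 were higher and 1 lower (20 and 1 adjusted over the list alone), including EGR1 (1.35 ± 0.06), KLF6 (0.97 ± 0.03) and DUSP1 (0.97 ± 0.04). The NFE2L2 list, an oxidative stress response, had 19 of 31 members higher and 5 lower (20 and 5 adjusted over the list alone), including AKR1C1 (1.11 ± 0.03), TXNRD1 (0.99 ± 0.03) and SQSTM1 (0.71 ± 0.03). The NF-kB list had 18 of 30 higher and 2 lower (19 and 2 adjusted over the list alone), with CCL20 at 0.98 ± 0.06 and CXCL1 at -0.96 ± 0.05. Its adjusted p = 0.142 with an estimated correlation. CXCL8 rose by 2.31 ± 0.40, to 1.98 ± 0.23 CPM.

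Hepatocyte secretory and urea cycle genes were lower in 25 of 31 cases and higher in 3 (25 and 3 adjusted over the list alone), with a median of -0.66. VTN fell by 2.29 ± 0.03, F2 by 1.77 ± 0.04 and TTR by 1.45 ± 0.02. The 3 that rose, named after their values were seen, were the fibrinogen genes FGA (1.41 ± 0.05), FGB (1.03 ± 0.03) and FGG (1.51 ± 0.11). Acute phase and complement genes were lower in 12 of 18 cases and higher in 3 (12 and 3 adjusted over the list alone), with C3 at -2.06 ± 0.02 and ceruloplasmin, CP, at -2.25 ± 0.04. Of 35 drug metabolism genes, 7 were higher and 19 lower (8 and 19 adjusted over the list alone). CYP3A5 fell by 0.92 ± 0.03 and UGT2B7 by 0.59 ± 0.03, and CYP3A4 fell by 2.48 ± 0.43 from 1.85 ± 0.45 CPM. Of 33 glycolysis and hypoxia genes, 5 were higher and 19 lower (6 and 19 adjusted over the list alone). NDRG1 fell by 0.81 ± 0.02 and ENO1 by 0.48 ± 0.02. Of 33 genes of the unfolded protein and integrated stress responses, 8 were higher and 20 lower (9 and 20 adjusted over the list alone). The chaperone genes HSP90B1 and HSPA5 fell by 0.99 ± 0.02 and by 0.71 ± 0.02, DDIT3 fell by 0.47 ± 0.09, and ATF3 rose by 1.69 ± 0.04. The median of that list was -0.24, its mean was 0.01 and camera placed it lower (adjusted p = 0.0723 with an estimated correlation).

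All 13 mitochondrially encoded genes were lower at day 10, with MT-CO1 at -0.72 ± 0.02 (adjusted p = 0.119 with an estimated correlation). Their share of the counts was 3.10% ± 0.05 in controls and 2.44% ± 0.07 with FFAs (SD, n = 3). Of 49 ribosomal protein genes, a list meant to show RNA quality and growth, 43 were lower and 0 higher (44 and 0 adjusted over the list alone), with RPL3 at -0.69 ± 0.03 (adjusted p = 0.164 with an estimated correlation). Of 21 intestinal markers, 3 were higher and 13 lower (3 and 13 adjusted over the list alone). LCT, FABP2 (2.61 ± 0.03) and ALPI, an intestinal alkaline phosphatase (0.87 ± 0.06), rose, and ISX, an intestinal transcription factor, fell by 0.69 ± 0.03. For this list the median was -0.25 and the mean -0.00, while camera placed it higher (adjusted p = 0.178 with an estimated correlation). With the replicate number as a block, camera placed it lower and did not call it (adjusted p = 0.534).

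Several lists moved in both directions at day 10 and did not pass camera. Of 23 lipogenesis genes, 7 were higher and 11 lower, and FASN rose by 0.09 ± 0.03 while SREBF1 fell by 0.46 ± 0.04, SCD by 0.26 ± 0.02 and SCD5 by 1.30 ± 0.06. With the GC trend removed FASN was at -0.01 and not called. Of 19 lipoprotein genes, 7 were higher and 10 lower. APOA4 rose by 1.73 ± 0.02, and APOA2 fell by 1.44 ± 0.03, APOE by 0.93 ± 0.02 and APOB by 0.60 ± 0.03. Extracellular matrix genes were higher in 20 of 34 cases and lower in 8, with CCN1 at 1.41 ± 0.04, COL1A1 at 0.30 ± 0.05, the crosslinking enzyme gene LOX at -1.26 ± 0.03 and fibronectin, FN1, at -0.66 ± 0.02. Bile acid genes were higher in 4 of 25 cases and lower in 13, including ABCB11 (-2.15 ± 0.19) and SLC10A1 (-1.46 ± 0.14), and CYP7A1 is not listed in the day 10 table. Fetal liver markers were higher in 7 of 14 cases and lower in 3, with AFP at -0.81 ± 0.02 and KRT18 at 0.53 ± 0.03. Polarity genes were higher in 14 of 39 cases and lower in 11, with CDH2 at 1.73 ± 0.06. Cholangiocyte markers had 8 and 4 of 18, with KRT19 at 0.17 ± 0.03 and PROM1 at -1.22 ± 0.07. Gluconeogenesis genes had 5 and 11 of 21, with PCK1 at 2.01 ± 0.05 and SLC37A4 at -1.04 ± 0.04. Higher and lower members were 7 and 2 of 19 cell cycle genes, 8 and 4 of 40 oxidative phosphorylation genes, 3 and 3 of 8 stellate cell markers, 2 and 1 of 7 endothelial and macrophage markers, and 1 and 0 of 5 genes of the metallothionein list. The 1 was the zinc transporter gene SLC30A1 (0.25 ± 0.03), and no metallothionein was called.

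These day 10 directions are relative to the median gene. Scaling by library totals, in which AFP weighs more, moved the median of all genes to 0.144 and made 74.0% of 7971 called genes higher, against 51.1% of 6901. Under that scaling the medians of the lipogenesis, bile acid and gluconeogenesis lists were at 0.09, 0.04 and 0.04, the ribosomal proteins had 2 higher and 30 lower, and the glycolysis list had 12 higher and 16 lower. Higher and lower members were then 5 and 5 of the intestinal list, 26 and 3 of the polarity list, 25 and 2 of the oxidative phosphorylation list and 9 and 7 of the bile acid list.

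**Figure D2:**
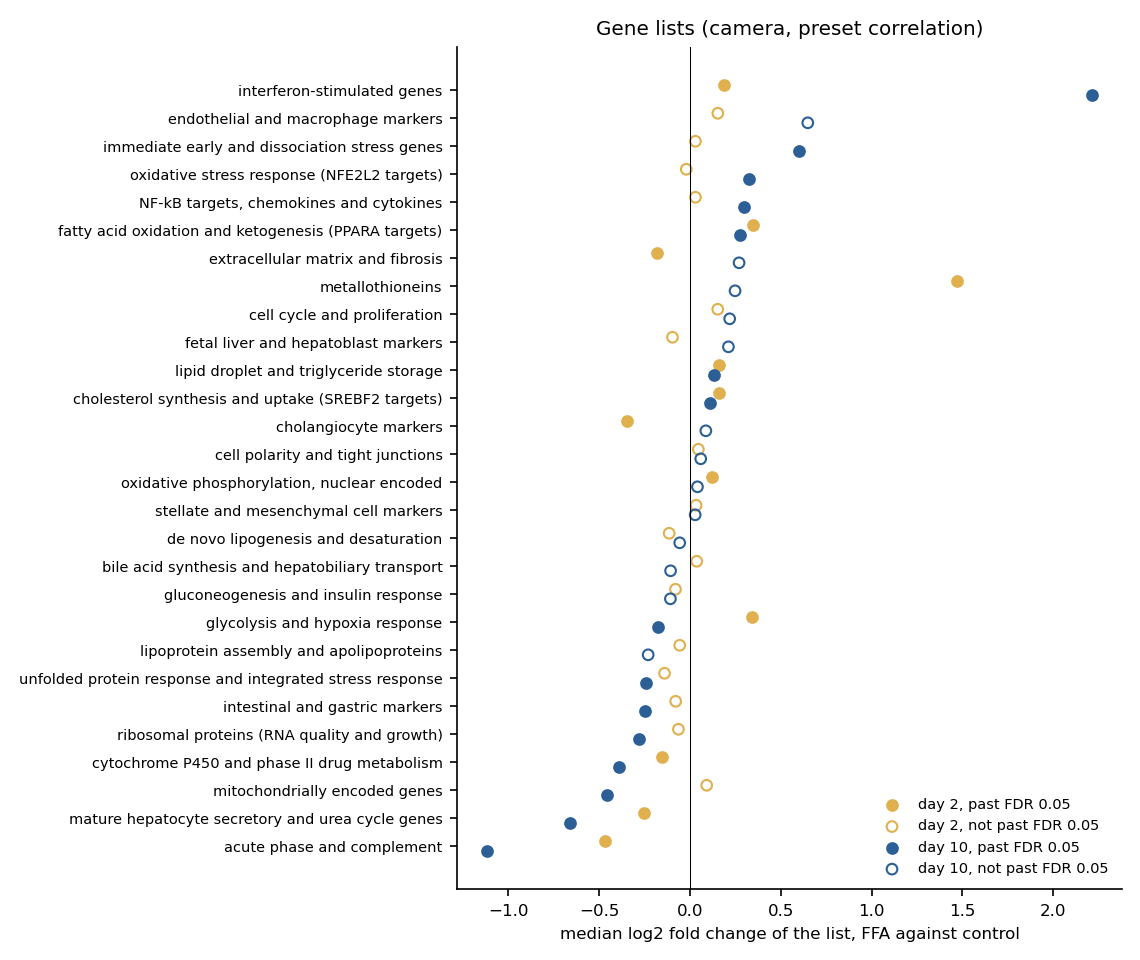
Median log2 fold change with FFAs (horizontal axis) of 28 gene lists (vertical axis) at day 2 and day 10, filled where camera with the preset correlation passed FDR 0.05 and open where it did not. The interferon list had the highest median at day 10, 2.21, and the acute phase list the lowest, -1.12, and the glycolysis and hypoxia list was at 0.34 on day 2 and -0.18 on day 10.

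The difference between days asked which FFA effects at day 10 differed from those at day 2. Length of treatment went with the count table and its annotation, and with any difference in batch or culture age between the days. Their effects on the FFA response cannot be told apart. The rises of LCT, CPT1A and interferon-stimulated genes were larger at day 10, as was the fall of hepatocyte secretory genes. The called glycolysis and hypoxia genes were all higher at day 2 and, with TMM scaling, mostly lower at day 10. With library totals the called genes of this list were more evenly split at day 10. The FFA effect on LCT was larger at day 10 by 2.83 ± 0.10 log2 units (SE, n = 3 per group, adjusted p = 6.5e-14) and that on CPT1A by 1.55 ± 0.12. For ALB the difference was -1.64 ± 0.09, and for NDRG1, higher at day 2 and lower at day 10, it was -1.63 ± 0.07. In all, the effect was higher at day 10 for 1077 genes and lower for 1151, of 15350 tested. This balance depended on the scaling, since with library totals it was higher for 2134 and lower for 695.

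The genes of smallest FDR also included CYP26A1 (-5.17 ± 0.22), KRT20, an intestinal keratin (2.51 ± 0.11), LOX (-1.46 ± 0.07), GC (-4.13 ± 0.15), VTN (-1.69 ± 0.09) and CP (-1.76 ± 0.09). The effect on PLIN2 differed by 0.23 ± 0.08 (adjusted p = 0.0676) and that on PDK4 by 0.04 ± 0.09 (adjusted p = 0.850), and neither was called. PLIN2 was called without FFA replicate 2 of day 2, with DESeq2, with library totals and with the GC trend removed. Differences for ANGPTL4 (-0.42), FASN (0.39), SREBF1 (0.16), DDIT3 (-0.32) and COL1A1 (0.13) were not called. With the GC trend removed ANGPTL4 (-0.61) and FASN (0.17) were called, and SREBF1 (-0.02) and COL1A1 (-0.02) changed sign without being called. SCD (-0.33 ± 0.06), APOB (-0.72 ± 0.07) and CYP3A4 (-2.44 ± 0.42) had a lower effect at day 10, and KRT19 (0.65 ± 0.14) and CXCL8 (3.34 ± 0.67, from few counts) a higher one.

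Among 33 glycolysis and hypoxia genes, the effect was lower at day 10 for 25 and higher for 1 (27 and 1 adjusted over the list alone), with a median difference of -0.59. Among 26 interferon-stimulated genes it was higher for 19 and lower for 0 (23 and 1 adjusted over the list alone), as for IFI6 (3.43 ± 0.21). The hepatocyte list had 3 higher and 13 lower of 33 (3 and 17 adjusted over the list alone), and the acute phase list 3 and 5 of 23 (5 and 6). Higher and lower counts were 13 and 0 of 21 immediate early genes (15 and 0 adjusted over the list alone), 14 and 1 of 29 NFE2L2 targets (15 and 1), 10 and 0 of 30 NF-kB targets (11 and 0) and 9 and 1 of 20 cholangiocyte markers (10 and 3). These lists passed camera with the preset and with the estimated correlation. A further 6 lists passed with the preset correlation only. The extracellular matrix list had 14 higher and 3 lower of 36 (16 and 4 adjusted over the list alone, adjusted p = 0.0524 with an estimated correlation). Of 6 genes of the metallothionein list, SLC30A1 and 5 metallothioneins, 4 were lower, all of them metallothioneins (adjusted p = 0.0834 with an estimated correlation). The drug metabolism list had 6 higher and 11 lower of 36 (adjusted p = 0.400 with an estimated correlation). The mitochondrially encoded list had 8 of 13 lower (adjusted p = 0.305 with an estimated correlation), and the ribosomal protein list 10 of 49 lower (adjusted p = 0.327 with an estimated correlation). The lipoprotein list had 3 higher and 7 lower of 20 (6 and 7 adjusted over the list alone). Its median was 0.04 and its mean -0.12, and camera placed it lower (adjusted p = 0.225 with an estimated correlation). It was not called in 6 of the 12 fits that left out a library. Without FFA replicate 2 of day 2 the metallothionein list was not called (adjusted p = 0.0926), and the medians were 0.28 for the extracellular matrix list, -0.15 for drug metabolism, -0.30 for the mitochondrially encoded list and -0.15 for ribosomal proteins.

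Of the lists that did not pass for the difference, fatty acid oxidation had 2 higher and 6 lower of 35 and lipid droplets 1 and 6 of 28. Genes of the unfolded protein and integrated stress responses had 5 and 7 of 34, and polarity genes 6 and 3 of 39. Fetal liver markers had 4 and 3 of 15, and bile acid genes 2 and 5 of 27. Higher and lower counts were 4 and 6 of 23 lipogenesis genes and 3 and 4 of 27 cholesterol synthesis genes. They were 1 and 1 of 9 stellate cell markers, 0 and 1 of 10 endothelial and macrophage markers, 1 and 4 of 21 intestinal markers, 2 and 1 of 24 cell cycle genes, 5 and 7 of 23 gluconeogenesis genes and 1 and 2 of 40 oxidative phosphorylation genes. Without FFA replicate 2 of day 2 the lipogenesis list (camera adjusted p = 0.0201) and the gluconeogenesis list (0.0345) were called lower. So was the unfolded protein and integrated stress response list (0.0201).

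Of the genes tested on both days, 13755 in all, 494 were higher at day 2, and 327 of these were higher at day 10 too, against 121 expected (Fisher's exact test, one-sided, p = 2.7e-88). Of 543 lower at day 2, 416 were lower at day 10, against 124 expected (p = 4.7e-163, the same exact test). A further 64 genes were higher at day 2 and lower at day 10, and 32 the reverse. Across genes the log2 fold changes of the 2 days had a Pearson r of 0.398 and a Spearman rho of 0.327. Genes are not independent replicates, so these correlations and the p-values of the exact test are descriptions. Without FFA replicate 2 of day 2, 862 higher and 1053 lower genes were shared, 1915 against 743, and 3849 genes differed between days, against 2228. With the GC trend removed, 3441 genes differed.

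**Figure D3:**
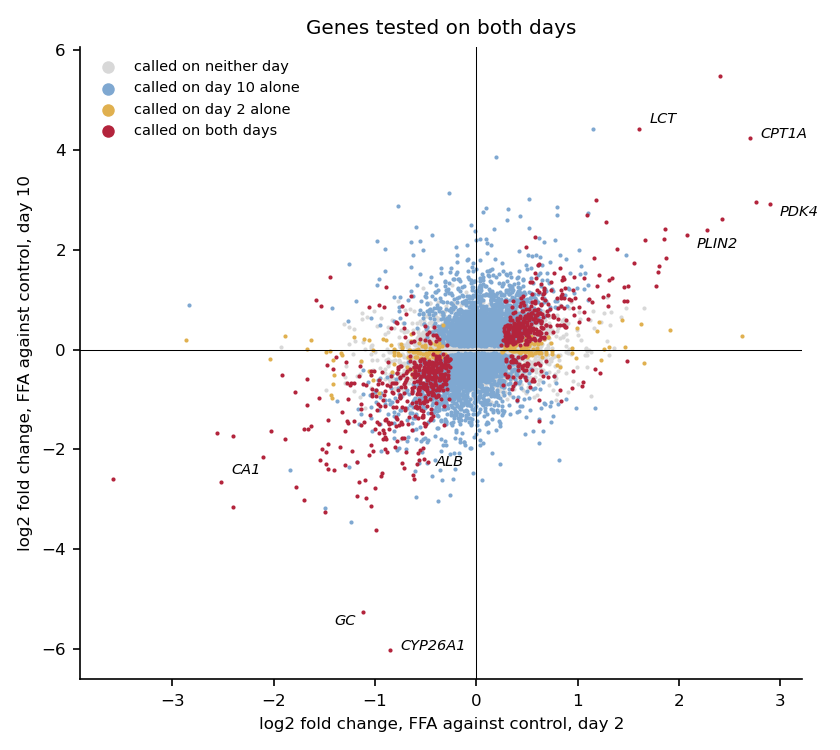
Log2 fold change with FFAs at day 2 (horizontal axis) against day 10 (vertical axis), with a point for each of the 13755 genes tested on both days, coloured by the day on which the gene was called at FDR 0.05. CPT1A lies at 2.70 and 4.24, and CYP26A1 at -0.85 and -6.03.

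**Figure D4:**
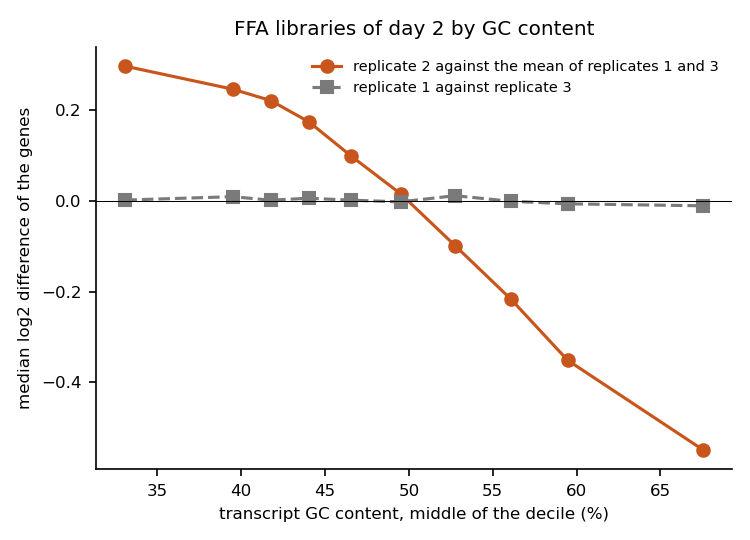
Median log2 difference of genes (vertical axis) by decile of transcript GC content in percent (horizontal axis), for FFA replicate 2 of day 2 against the mean of replicates 1 and 3, and for replicate 1 against replicate 3. The first line runs from 0.30 in the decile of lowest GC content to -0.55 in the highest, and the second stays near 0.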

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

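The tests of GC content, transcript length and a control label for FFA replicate 2 of day 2, of immune cells, of library scaling and of marker spread were chosen only after the results they bear on had been seen, as was the GC correction itself.

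The following results differed between the 2 days by the test of the difference itself, given as the log2 FFA effect at day 10 minus that at day 2, and 2228 genes did so in all. The effect was higher at day 10 for LCT (2.83), KRT20 (2.51), CPT1A (1.55), CXCL8 (3.34), KRT19 (0.65), IFI6 (3.43), RSAD2 (3.27), IFIT2 (1.83), OASL (1.99), VCAN (1.23) and CA3 (0.94). OASL was not called without control replicate 1 or 3 of day 2 (1.59 and 1.89). It was lower at day 10 for NDRG1 (-1.63), CYP26A1 (-5.17), LOX (-1.46), GC (-4.13), VTN (-1.69), CP (-1.76), ALB (-1.64), SCD (-0.33), APOB (-0.72), CYP3A4 (-2.44), SLC2A5 (-1.96), CELF3 (-2.65), CYP26B1 (-2.09), DNAH12 (-0.93), ANXA13 (-0.46), ORM1 (-1.51), GLYAT (-2.62) and NOX1 (-1.75). For VCAN and CA3, which fell at day 2, a higher value means a smaller fall. Median differences of the lists past FDR 0.05 were 1.64 for interferon-stimulated genes, 0.46 for immediate early genes, 0.42 for extracellular matrix, 0.37 for cholangiocyte markers, 0.34 for NFE2L2 targets, 0.30 for NF-kB targets and 0.0376 for lipoprotein genes. They were -0.59 for glycolysis and hypoxia, -0.37 for hepatocyte genes, -0.75 for acute phase genes, -0.29 for drug metabolism, -0.55 for mitochondrially encoded genes, -0.23 for ribosomal proteins and -1.45 for the metallothionein list. Without FFA replicate 2 of day 2 the metallothionein list was not called, and the medians of extracellular matrix, drug metabolism, mitochondrially encoded genes and ribosomal proteins were 0.28, -0.15, -0.30 and -0.15.

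Other splits of the libraries were counted for the 3 gene counts. For day 2 and day 10 the 10 splits of 6 libraries are too few for a share under 0.05. The real split alone, 1 of 10, gave as many genes on each day, 1089 with a highest other of 0 and 6901 with a highest other of 0. For the difference between days, 6 of 100 splits gave at least the real 2228 genes, the highest of the others 4777, so chance was not excluded by this count. All 6 kept the day 10 libraries in their own groups or exchanged the groups whole, as 12 splits did. Such splits still hold the large day 10 effect, so their counts, 4777 among them, do not measure chance. The other 88 gave at most 23 genes.

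FFA replicate 2 of day 2 stood apart from the other 2 FFA libraries of its day. Transcript length (Spearman correlation 0.0341) and greater depth argued against themselves as the cause, since after thinning to the smallest FFA library its variance ratio was still 11.1 times that of the other pair. A control library under an FFA label was argued against too, since 268 genes that separated the other 2 FFA libraries from the controls sat at a median position of 0.873 between control (0) and FFA (1). Its deviation followed GC content, with a Spearman correlation of -0.795, which suggests a technical difference in this library, and removing the GC trend of each library moved the day 2 count from 1089 to 2649. What made the GC trend, such as amplification or handling, stays open, and no biological explanation was tested.

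Interferon-stimulated genes were higher with FFAs at day 10, with a median log2 fold change of 2.21. A change of scaling moves all genes by nearly the same amount. Library totals moved the median of all genes to 0.144 and the list's median to 2.36. This shows only that the choice between these 2 scalings was too small to account for the rise. After removal of the GC trend the list's median was 2.22. That was a weak test, since day 10 fold changes had little such trend to remove (Spearman correlation 0.0471 with GC content across genes). Leukocytes as a source cannot be told apart from a response of the organoid cells, since their 5 tested markers moved both ways around a median of 0.65, with CD74 (0.65) and CSF1R (0.98) higher, AIF1 (-2.07) lower, and LYZ and FCER1G not called. Of these markers only CD74, at 20.7 CPM of the library totals with FFAs, passed 5 CPM. CD14, CD163 and CD68 were too low to be tested, at 0.0394, 0.478 and 0.217 CPM of the library totals with FFAs. The CD68 value says little about leukocytes, since this gene was counted far higher in the day 2 table, which used another annotation. A response of the organoid cells to FFAs may be involved and was not tested, and whether the controls received the carrier of the FFAs is not stated, so an effect of the carrier stays open, as does one of handling, since 20 of 21 immediate early and dissociation stress genes were higher too.

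Hepatocyte secretory genes fell at day 10 while the intestinal genes LCT and FABP2 rose. Library totals move all genes by nearly the same amount. The list's median of -0.52 under them shows only that this shift was smaller than the fall. With the GC trend removed the median was -0.70, a weak test since day 10 fold changes had little such trend to remove. A lower share of hepatocyte-like cells as the whole cause was tested by the spread of the list, an interquartile range of 1.13. That spread cannot decide it, since the test assumed that only these cells express the members, which was not shown. The rises of FGA, FGB and FGG argued against a lower share as the whole cause for these genes, while 25 members were lower. Whether that share changed in part cannot be told apart from a change within cells, since 14 intestinal markers at 5 CPM or more had an interquartile range of 0.244 around a median of -0.19, with 3 higher and 10 lower, and with library totals the whole intestinal list had 5 higher and 5 lower. An effect of FFAs on transcription within the cells may contribute and was not tested, nor was one of handling or RNA quality, although 43 of 49 ribosomal protein genes were lower too.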

How the results depend on the processing

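The GC correction, and the overlap and the counts of called members within lists without FFA replicate 2 of day 2, were chosen only after the data were seen, and the other alternatives were fixed before the data were examined. At day 2, 1089 genes became 461 at FDR 0.01, 197 with a fold threshold of 2, 2219 in a fit of all 12 libraries, 2649 with the GC trend removed, and 420 to 3217 with 1 library left out (3217 without FFA replicate 2). At day 10, 6901 became 1014 with the fold threshold. The difference between days, 2228, became 1145 at FDR 0.01, 3441 with the GC trend removed and 1662 to 3849 with 1 library left out (3849 without FFA replicate 2 of day 2). Shared calls, 743, became 341 at FDR 0.01 and 1915 without FFA replicate 2 of day 2. With an estimated correlation 5, 9 and 9 lists passed at day 2, at day 10 and for the difference, against 12, 15 and 15, and with fry 27 lists passed at day 10. Fewer libraries, stricter thresholds and a pooled spread are part of these settings. For the other changes the cause was not tested.

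With the replicate number as a block, the counts were 939, 6874 and 2021. The numbers were not taken as pairs, since correlations between libraries of the same number reached only 0.0109 and those between other numbers 0.0106, although 4 of 6 libraries of day 2, and 0 of 6 of day 10, correlated best with their own number. Among results called with either setting, the direction of a gene or the tested direction of a list turned in 3 cases. The list of mitochondrially encoded genes was at a median of -0.0773 at day 2 without FFA replicate 2, while without FFA replicate 3 it was at 0.173. The intestinal list of day 10 was tested lower, and not called, with the replicate block (median -0.25). FASN at day 10 was at -0.00788 with the GC trend removed. Over all alternatives the named genes kept their side of FDR 0.05 in 1896 cases at day 2, 2096 at day 10 and 973 for the difference, against 135, 16 and 2 losses of a call and 68, 1 and 25 gains. Values called with neither setting changed sign in further cases, such as the lipogenesis list of day 10 with library totals (0.0889). At day 2, 123 of the 135 losses of a call came from leaving out a library. Changes of 1.5-fold were recovered in 56.1% of simulated cases at day 2 and 29.9% for the difference, so smaller changes were often missed with these settings. The simulated spread included that of FFA replicate 2 of day 2. Without that library, 3217 rather than 1089 genes were called at day 2, and 3849 rather than 2228 for the difference. The limit was therefore not one of depth and number of libraries alone.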

Other observations

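The retinoic acid list was written and its test fixed before it was run, but after CYP26A1 and CYP26B1 had been seen, and 1 of its members, LRAT, also sits in the stellate list. The genes named in the next paragraph were chosen after their values were seen.

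Several markers of intestinal epithelium were abundant in organoids described as hepatocyte-like. Of 24 intestinal and gastric markers, 14 reached 5 CPM of the library totals in the day 10 controls and 8 reached 100 CPM. In the day 10 controls the intestinal transcription factor gene CDX2 stood at 228 ± 3.3 CPM (SD, n = 3), CDH17 at 1848 ± 15.6 CPM, the peptide transporter gene SLC15A1 at 812 ± 9.3 CPM and the mucin gene MUC13 at 6150 ± 84 CPM, beside ALB at 20824 ± 146 CPM. Hepatocyte genes varied widely there. Of 35 hepatocyte secretory and urea cycle genes, 25 reached 5 CPM of the library totals and 15 reached 100 CPM. Others were low, such as AHSG (1.69 CPM), APOH (1.60 CPM), AMBP (1.59 CPM) and ARG1 (0.81 CPM). The day 2 controls likewise had MUC13 at 3891 ± 56 CPM of the library totals. Some of these genes, such as MUC13 and VIL1 (1210 ± 12.6 CPM at day 10), are also expressed in liver or bile duct epithelium, so the levels alone name no cell type. Of the cholangiocyte markers, 14 of 24 reached 5 CPM of the library totals in the day 2 controls. Markers of other lineages outside the epithelium were fewer. In the same controls, 5 of 27 stellate and mesenchymal markers reached 5 CPM of the library totals, 1 of 28 endothelial and macrophage markers did, and 0 of 18 pluripotency markers did. MKI67, a marker of dividing cells, stood at 0.95 ± 0.22 CPM in the day 2 controls and fell to 0.25 ± 0.01 CPM with FFAs, a few counts per library. It was the only called member of 23 tested cell cycle genes, whose median log2 fold change was 0.15, so it does not stand for the list.

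CYP26A1 and CYP26B1, which degrade retinoic acid and are themselves induced by it, fell by 6.03 ± 0.20 and 3.14 ± 0.07 log2 units at day 10. The hypothesis that other retinoic acid-responsive genes fall with them was tested with a list of 18 genes, 12 of them tested. Of these, 9 were lower and 2 higher, with a median log2 fold change of -0.41, as for RARB (-0.93 ± 0.06) and TGM2 (-0.94 ± 0.02). That median lay at percentile 0.31 of 10000 random lists matched on mean expression, whose central range was -0.27 to 0.19. The members of the random lists were drawn independently. The percentile therefore makes no allowance for genes that move together, and it is a description. The result is consistent with lower retinoic acid signalling at day 10 as a hypothesis. CRABP2 (1.22 ± 0.23) and PLAAT4 (1.37 ± 0.20) rose, and retinoic acid itself was not measured.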
